A study of Mus musculus with 4 samples.

How the data were processed

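The series holds 4 droplet libraries of dissociated mouse extrahepatic bile duct: 3 wild-type libraries and 1 library with mosaic gain of function of Ctnnb1, the gene for beta-catenin, here called the GOF library. Per the labels' protocols, whole ducts were dissected, digested with dispase and a bacterial protease, filtered, and captured with the 10x Chromium 3′ chemistry, which counts molecules near the 3′ end of each transcript. The labels do not describe the construct or say how recombination was checked. Nothing in them says that the wild-type libraries came from separate animals, so p-values here measure only the spread between these samples, which may be technical. The lone GOF library is assumed throughout to vary like the wild-type libraries.

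The deposited matrices hold raw UMI counts per gene and cell barcode, with barcodes already called as cells. Per the file headers, the GOF matrix was made with Cell Ranger 7.0.0 and lists 32285 genes, while the wild-type matrices were made with version 3.0.2 and list 31053 genes. Per the submitters' processing notes, Cell Ranger 7.1 and the mouse build mm10 were used. The gene reference release and whether intronic reads were counted are not given in the sources used here. The group comparison and this difference in processing cannot be told apart by design. Only the 30406 genes with an identifier in both references were used; 597 of them carried different symbols and took the symbol of the wild-type reference. A further 1879 genes were listed in the GOF reference alone and 647 in the wild-type reference alone. All shared identifiers (100.0%) matched the GENCODE annotation of GRCm38, from which coordinates and intron lengths were taken.

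The GOF library holds 10796 barcodes and 113596685 UMIs. Wild-type libraries 1, 2 and 3 hold 6253, 3270 and 2649 barcodes with 43737469, 17358894 and 9558637 UMIs. Median UMIs per barcode were 7038.5 in the GOF library and 3690.0, 2690.5 and 1933.0 in the wild-type libraries, and the median mitochondrial share was 3.01% against 10.1%, 11.5% and 14.8%. Counts of the wild-type libraries differed from each other beyond sampling noise, with chi-square per degree of freedom from 62.6 to 135 across the pairs, so they were kept as 3 samples.

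Cells with at least 500 detected genes and at most 25% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its own threshold marked 299, 0, 2 and 9 cells, so the highest-scoring cells were left out instead, at 0.8% per 1000 barcodes: 870, 228, 65 and 45 cells. This left 9208 GOF cells and 4328, 2413 and 2056 wild-type cells. Cells past the gene and mitochondrial limits, called doublets included, were clustered by the Leiden method of igraph 0.11.9 on 30 principal components of 2000 variable genes. Mitochondrial, ribosomal and sex-linked genes were not used, and libraries were not integrated. Called doublets were left out of the sums and shares after this clustering. Clusters were named from fixed marker lists, and a named class is written "X-like". The markers, the gene lists, the tests, the rule for named genes and most alternative settings were chosen before the data were examined. The thresholds of the naming score were set after the data were seen; clusters left unnamed held 10.1% of GOF cells and 0.300%, 1.57% and 0.00% of wild-type cells.

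UMIs were summed per library and class, since cells are not replicates, and sums were compared with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. GOF sums were compared with wild-type sums in every class with at least 20 cells in each library, leaving 2 residual degrees of freedom. The difference between the epithelial and fibroblast effects was tested as an interaction with the library as a block, which removes anything that shifts a gene alike in both classes of a library. Wild-type epithelium and fibroblasts were compared with the library as a block. Class shares were tested with edgeR on cell numbers. The 31 gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (limma 3.58.1).

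Shares of cells with a UMI were compared after each cell was thinned to 2000 UMIs, leaving out shallower cells, with exact Clopper-Pearson 95% intervals that cover counting error only. A fold against a group with no UMI is a lower bound from a floor of 3 counts over that group. Ratios resting on 1 to 3 UMIs are given with their counting interval. The rule for named genes took Ctnnb1 and Prom1; the 10 largest rises and 10 largest falls in epithelium among genes past the threshold with at least 20 CPM in the higher group and the GOF value outside the wild-type range; the 5 largest in each direction for fibroblasts and for the interaction; up to 3 members per list; at most 25 genes of the wild-type duct; and the Wnt feedback list with Mki67 and Top2a for shares. Predicted, mitochondrial, ribosomal and sex-linked genes were passed over.

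The tests were checked on data simulated from the real means and library sizes with 200 genes changed. In the GOF comparisons unchanged genes had the wild-type mean of their class in every library. The false shares below therefore do not cover a shift of the whole GOF library. In the simulated epithelial comparison of 15470 genes, 12.2% of changes of 2-fold, 56.4% of 4-fold and 74.9% of 8-fold were recovered, and 4.02% of calls were false. In the simulated fibroblast comparison of 6414 genes the shares were 7.46%, 57.3% and 78.5%, with 7.03% false. The simulated interaction over 14490 genes recovered 2.69%, 28.7% and 50.9%, with 2.15% false, and the simulated wild-type comparison over 11400 genes recovered 18.5%, 63.9% and 82.1%, with 3.01% false. Alternatives covered the normalisation (DESeq2 1.42.0, no TMM), limma-voom, count filters, cell filters, doublets, clustering of each library alone, thinning, each wild-type library left out, other comparator classes and the replicate block. Alternatives added after the data were seen were tests on genes with at most 5 kb of intron, lists in the interaction fit, epithelium without cycling clusters and the shares without Znrf3.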

Results

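Single cells of the mouse common bile duct were profiled to compare normal ducts with ducts carrying mosaic Ctnnb1 gain of function. After filtering, 4103 epithelial-like cells (58607809 UMIs) of the GOF library were set against 2958, 1501 and 1160 epithelial-like cells (33793395, 11469432 and 6184241 UMIs) of wild-type libraries 1, 2 and 3. Fibroblast-like cells were fewer, with 317 cells (1856216 UMIs) in the GOF library and 91, 82 and 188 cells (346736, 209988 and 282114 UMIs) in the wild-type libraries. Levels are given as CPM, UMIs of a gene scaled to the total UMIs of its class, as mean ± SD of the 3 wild-type libraries. In GOF comparisons CPM and folds include the TMM factors, while lower bounds and ratios with a counting interval come from pooled counts without them. The GOF library has no replicate.

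The wild-type libraries show which compartment of the normal duct expressed Wnt, Notch, Hedgehog and BMP genes. Fibroblast-like cells held the R-spondins, which potentiate Wnt signalling at the receptor: Rspo1 was at 78.6 ± 34.4 CPM in fibroblasts and 0.730 ± 0.637 in epithelium, and Rspo3 at 63.5 ± 3.21 and 0.0390 ± 0.0440 (n = 3). Mesothelial-like cells held more Rspo1 still, at 416 ± 305 CPM, and lymphatic endothelial-like cells held Rspo3 at 41.8 ± 5.74. Rspo1 is among the fixed markers that named the mesothelial-like class, so part of its excess there may be built in. The secreted Wnt antagonist Sfrp1 stood at 992 ± 137 CPM in fibroblasts and 1.17 ± 1.14 in epithelium, and the non-canonical ligand Wnt5a at 115 ± 20.6 and 1.92 ± 1.95. Epithelium was higher for the ligands Wnt7b (48.3 ± 20.3 against 9.05 ± 4.58 CPM) and Wnt4 (133 ± 92.4 against 41.6 ± 28.6) and for Lgr4, a receptor for R-spondins (62.1 ± 15.4 against 15.8 ± 10.8).

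Feedback genes that beta-catenin induces divided between the compartments of the normal duct. Axin2, a scaffold of the beta-catenin destruction complex, was at 39.7 ± 17.0 CPM in fibroblasts and 5.12 ± 1.75 in epithelium, a log2 difference of -2.87 (SE 0.411), and Nkd1, a Dishevelled antagonist, at 17.7 ± 10.7 and 0.126 ± 0.193. The ubiquitin ligase genes Rnf43 and Znrf3, which remove Frizzled receptors, went the other way, with Rnf43 at 34.5 ± 11.4 CPM in epithelium and 7.53 ± 10.1 in fibroblasts. Znrf3 rested on 3 fibroblast UMIs, an epithelial excess of 6.42 (counting interval 2.19 to 31.2). Among Notch genes, Hes1 (425 ± 150 against 115 ± 29.4 CPM) was higher in epithelium, and the ligand Dll1 (36.3 ± 27.0 CPM) rested on 1 fibroblast UMI, a ratio of 43.0 (7.71 to 1699). The Hedgehog targets Gli1 (log2 difference -8.37) and Ptch1 (-2.57) and the ligand Bmp4 (-3.37) were higher in fibroblasts. Further genes higher in fibroblasts were Fzd1, Fzd4, Dkk2, Sfrp2 and Wif1, and further genes higher in epithelium were Fzd5, Sox9 and Notch1. Sox9 is among the fixed markers that named the epithelial-like class. By edgeR's quasi-likelihood test with the library as a block, 17 of 79 tested genes of the 5 pathway lists were higher in epithelium and 41 in fibroblasts at a Benjamini-Hochberg adjusted p under 0.05. The counts were 18 and 42 adjusted over the list alone. Wls, which exports Wnt ligands, did not pass (107 ± 6.98 against 114 ± 89.6 CPM, adjusted p = 0.830). The 24 named genes other than Wls differed in the same direction in each of the 3 libraries, and their adjusted p ran from 5.72e-09 for Sfrp1 to 0.00427 for Rnf43.

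**Figure D1:**
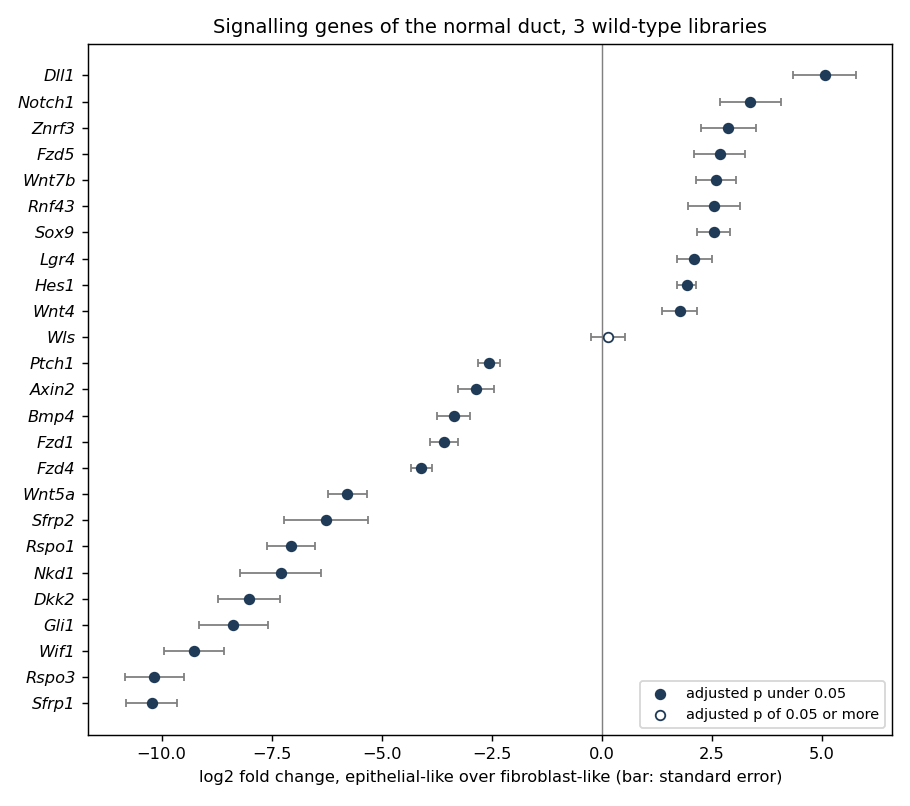
Log2 fold change of 25 signalling genes in epithelial-like over fibroblast-like cells of the 3 wild-type libraries (point, estimate; bar, standard error), with filled points past the adjusted threshold. Sfrp1 (-10.23) and Rspo3 (-10.17) lie furthest toward fibroblasts and Dll1 (5.05) furthest toward epithelium; Wls (0.14) did not pass.

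The targeted gene was lower in the GOF library. Ctnnb1 (ENSMUSG00000006932; chromosome 9, 120929216 to 120960507, GRCm38) stood at 228 CPM in GOF epithelium and at 611, 565 and 498 CPM in the wild-type libraries, a log2 fold change of -1.29 (SE 0.245, edgeR adjusted p = 0.0258; 0.0888 without wild-type library 2). In fibroblasts its log2 fold change was -0.86 (edgeR adjusted p = 0.225), and the difference between both effects, -0.38, did not pass (edgeR adjusted p = 1). A 3′ tag does not read the 5′ part of the transcript and the construct is not described, so this level checks neither the allele nor the label. Prom1 (ENSMUSG00000029086; chromosome 5, 43993620 to 44102032), which the label names and which encodes a membrane protein of epithelial progenitors, was at 222 CPM against 258, 274 and 302 CPM (log2 fold change -0.33, edgeR adjusted p = 0.309).

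Wnt feedback genes rose in GOF epithelium. Axin2 (ENSMUSG00000000142; chromosome 11, 108920349 to 108950783) was at 94.5 CPM against 5.45 ± 1.82 in the wild type (n = 3), 17.3-fold higher. Nkd1 (ENSMUSG00000031661; chromosome 8, 88521354 to 88594884) was at 80.3 against 0.130 ± 0.198 CPM, 619-fold higher. Notum (ENSMUSG00000042988), a secreted enzyme that inactivates Wnt ligands, was 31.2-fold higher; Sp5, a transcription factor downstream of beta-catenin, 35.8-fold; Lgr5, an R-spondin receptor of stem cells, 29.4-fold; and Tnfrsf19, a receptor of the wider target list, 97.49-fold. All 10 tested genes of the feedback list rose, with a median log2 fold change of 5.04, or 4.98 with Apcdd1 at its lower bound. The smaller changes were Rnf43 at 3.01-fold, Tcf7 at 5.93-fold and Znrf3 at 5.94-fold. Lef1 rested on 2 wild-type UMIs, a ratio of 66.7 (counting interval 18.2 to 556), and Apcdd1, with 106 UMIs against 0, was at least 31.0-fold higher. Without wild-type library 2 the edgeR adjusted p was 0.0737 for Rnf43, 0.0504 for Tcf7, 0.0751 for Lef1 and 0.0603 for Apcdd1, and without wild-type library 1 it was 0.0665 for Apcdd1. Of 24 tested members of the wider list of Wnt targets, which includes the feedback genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 2.26.

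Adjusted p for these genes ran from 0.00183 for Nkd1 to 0.0425 for Apcdd1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the GOF value lay above all 3 wild-type libraries for the 10 feedback genes. Camera gave 5.84e-16 for the feedback list and 8.34e-12 for the targets with the preset correlation, adjusted over 31 lists; both were lost at an adjusted p = 0.444 with an estimated correlation. Tuft-like cells, a chemosensory epithelial type, showed the same direction: 7 of 7 tested feedback genes rose, with a median of 2.60 and Axin2 at 4.62 on the log2 scale. In fibroblasts 0 of 4 tested members rose by edgeR, with 1 passing when adjusted over the list alone, and the median was -0.23. The epithelial-like class consisted mainly of clusters 0, 1, 2 and 12 in the GOF library and of clusters 13, 17, 24, 26 and 29 in the wild-type libraries, and the tuft-like class of cluster 20 against cluster 21.

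**Figure D2:**
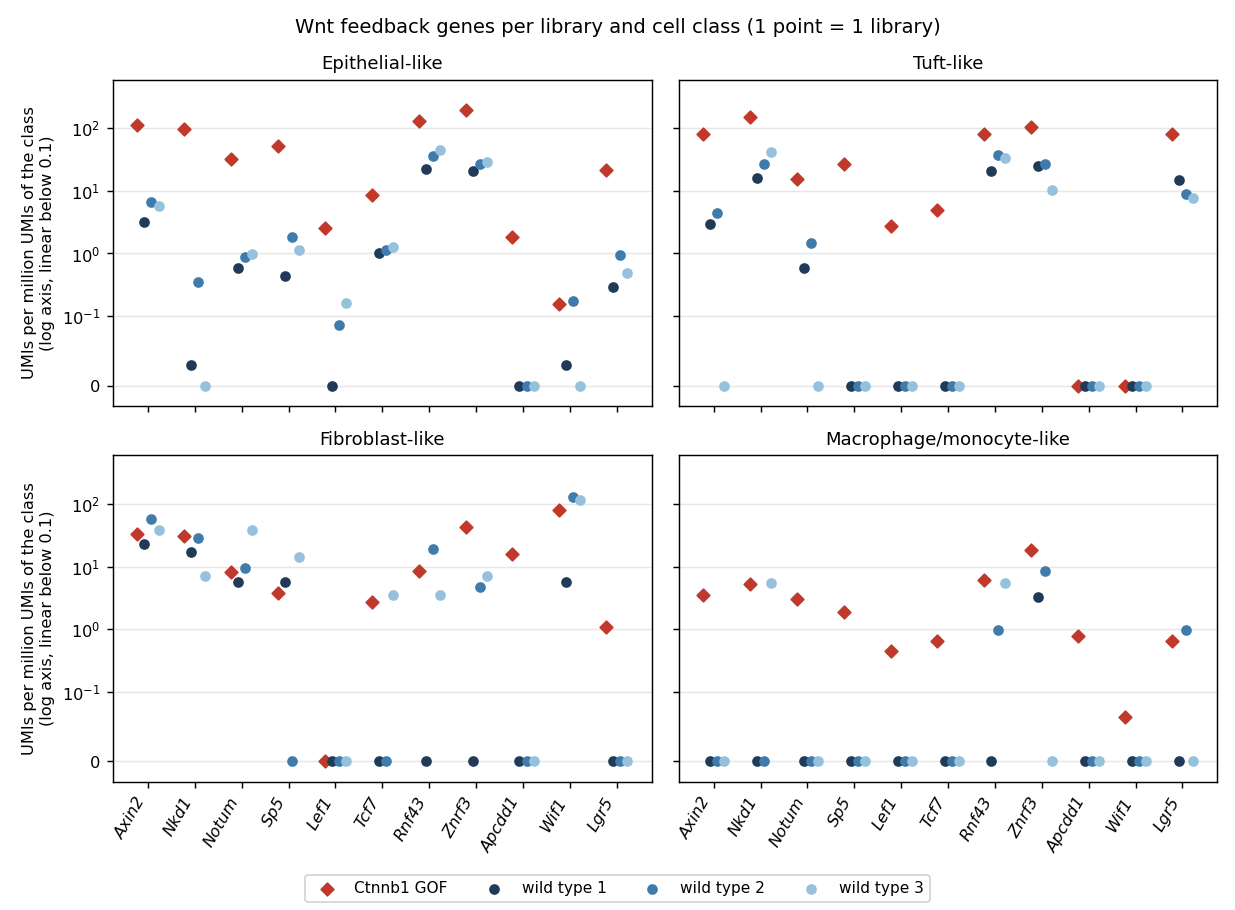
CPM without further scaling (log axis, linear below 0.1) for the 11 Wnt feedback genes in 4 cell classes, with 1 point per library and GOF as diamonds. Axin2 in epithelium stood at 114 in the GOF library against a wild-type pool of 4.22, while in fibroblasts the GOF value of 32.9 lay among the wild-type values.

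Beyond the Wnt genes, epithelial gene groups moved in both directions. Interferon-response genes rose in 15 of 21 tested members (median 2.23), led by Ifi44 (4.76), Rsad2 (4.54) and Usp18 (4.23), antiviral effectors and a brake on interferon signalling. Antigen-presentation genes rose in 10 of 17 (median 1.97), among them H2-Q7 (4.66), the class II gene H2-Ab1 (3.70) and the class I activator Nlrc5 (4.17). Immediate early genes, which respond to stress and to dissociation, rose in 9 of 22 (median 1.77): Atf3 was at 2281 CPM against 14.3 ± 4.86, Egr2 at a log2 fold change of 4.26 and Dusp1 at 3.88. YAP targets rose in 9 of 18 (median 0.82), with Cyr61 at 3.85 and Ankrd1 at 3.70. Subunits of oxidative phosphorylation fell in 7 of 22 (median -0.74), led by Ndufa1 (-1.82), Cox7c (-1.71) and Ndufa5 (-1.31). This list was lower in each of the 9 classes, with medians from -1.01 to -0.41, its difference between epithelium and fibroblasts did not pass (camera adjusted p = 0.148), and the GOF library had the lower mitochondrial share. Without wild-type library 2 Ankrd1 and Ndufa5 did not pass (edgeR adjusted p = 0.0561 and 0.0805), and without library 1 Ankrd1 was at 5.71. Adjusted over the list alone, the counts were 18, 14, 17, 10 and 13. Camera's adjusted p for these 5 groups ran from 4.37e-14 to 0.0016 with the preset correlation, and was 0.444 for each with an estimated correlation. The self-contained test fry gave an adjusted p of 0.0459 for the interferon, antigen, immediate early and oxidative phosphorylation lists, 0.0551 for Wnt targets, 0.0746 for the feedback list and 0.0623 for YAP targets.

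Smaller groups passed camera with few single genes. Mitotic genes leaned up (median 1.37, camera adjusted p = 0.0016), with 1 of 24 past the threshold, Cenpf at 2.04, and 8 adjusted over the list alone; Mki67 (1.10, edgeR adjusted p = 0.0569) and Top2a (1.65, edgeR adjusted p = 0.0969) did not pass. Glutathione and Nrf2 genes leaned down (median -1.03, camera adjusted p = 0.00109), with Mgst1 at -1.15. Intestinal genes (median -1.23, camera adjusted p = 0.0202) included falls of Lgals2 (-2.07) and the progenitor marker Olfm4 (-1.79). Glycolysis and hypoxia genes (median -0.61, camera adjusted p = 0.0226) held falls of the glycolytic enzymes Hk2 (-2.28) and Eno1 (-2.24) and a rise of Ndrg1 (1.27). Secretory stress genes (median -0.50, camera adjusted p = 0.043) included Xbp1 at -0.91, and pancreatic genes (median -1.55, camera adjusted p = 0.0415) held 1 fall, Cela2a, with 3 GOF UMIs, a ratio of 0.00458 (0.000942 to 0.0135). With an estimated correlation the adjusted p was 0.702 for the mitotic and secretory stress lists and 0.678 for the other 4. Without wild-type library 1 the intestinal, glycolysis and secretory stress lists did not pass, nor did Mgst1 (edgeR adjusted p = 0.0642), Olfm4 (0.0653), Xbp1 (0.0639) and Cela2a (0.0556); without wild-type library 2 Mgst1 (0.112), Ndrg1 (0.0747) and Xbp1 (0.179) did not pass.

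The remaining lists did not pass camera in epithelium. Biliary identity genes, the markers of the duct lineage, held 0 rises and 2 falls of 24, Foxa2 (-1.01) and Hhex (-0.79). Gastric mucous genes held 1 fall of 16, Fcgbp (-2.34). The p53 list held 4 rises of 17, led by the growth inhibitors Btg2 (2.75) and Cdkn1a (1.81). Injury genes held 4 rises of 22, among them Reg3b (2.98) and Icam1 (2.80), and ciliary genes 4 of 16, with Pkhd1 (2.94) and Rfx3 (2.46). Hedgehog and BMP genes held 4 rises of 22, among them Id1 (1.56) and Ihh (1.21). Wnt ligand genes held 2 rises of 12, Wnt5b with 3 wild-type UMIs, a ratio of 81.6 (27.6 to 398), and Wnt6 with 1, a ratio of 77.2 (13.5 to 3085). Wnt receptor genes held 3 rises and 1 fall of 21, with Fzd10 (4.36), Dkk2 (3.42) and Ror1 (2.40). Squamous genes held 1 rise of 7, Krt17 (2.80), and mesenchymal genes 1 of 14, Zeb1 (3.93). Without wild-type library 2 the edgeR adjusted p was 0.0919 for Foxa2, 0.184 for Hhex, 0.0524 for Cdkn1a, 0.0800 for Id1, 0.0788 for Wnt6, 0.127 for Dkk2 and 0.0633 for Ror1, without library 1 it was 0.0542 for Hhex, 0.0650 for Fcgbp, 0.0778 for Wnt6, 0.0836 for Dkk2 and 0.0681 for Krt17, and without library 3 it was 0.0502 for Hhex. The pericentral liver list, which follows Wnt in hepatocytes, held 1 of 9, Axin2. Rises and falls together numbered 3 and 2 of 12 for the beta-catenin complex, 2 and 1 of 18 for bile acid genes, 2 and 2 of 20 for lipid genes, 3 and 2 of 20 for cell junctions and 1 and 2 of 24 for ribosomal proteins. Notch genes (0 of 15) and replication genes (0 of 24) gave no calls by edgeR, with 0 adjusted over the list alone. Of the genes named here, several moved alike in fibroblasts. Ror1 was 18.0-fold, Reg3b 8.37-fold and Zeb1 6.50-fold higher there, and Fcgbp 4.89-fold lower. Rfx3, with 3 wild-type fibroblast UMIs, had a ratio of 11.4 (3.77 to 56.7). Cdkn1a (1.85-fold lower) and Id1 (1.51-fold lower) went the other way. Before TMM, Dkk2 was at 1.76 CPM in GOF epithelium and 87.8 in GOF fibroblasts. Changes of genes that moved alike are not shown to be of epithelium alone.

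Across all genes, 1749 of 15473 rose and 591 fell in GOF epithelium. Among the largest rises beside Nkd1 were Serpinb11, with 2359 UMIs against 0 and so at least 690-fold higher, Chsy3 (8.93), Sorbs2os (8.08), Fdx1l (7.69), Cpne1 (7.504), Lsmem1 (7.40), Atf3 (7.35) and the proton pump subunit Atp6v0c (7.32). Among the largest falls were AC160336.1 (-8.67), the phosphatase Ptp4a1 (-7.96), Amd2 (-6.16), the glutathione transferase Gstp1 (-5.33), Chtf8 (-4.09), Usp50 (-4.07), Mndal (-4.03), Bloc1s1 (-3.90) and Ifi203 (-3.89). Most of those tested in fibroblasts moved alike there, so these are not changes of the epithelium alone: AC160336.1 (-7.25), Gstp1 (-5.44), Usp50 (-3.38) and Bloc1s1 (-3.36) fell and Atf3 (4.40) rose; on few UMIs fell Ptp4a1, with 3 GOF UMIs (a ratio of 0.0156; 0.00315 to 0.0471), and Amd2, with 1 (0.0151; 0.000369 to 0.0906), and rose Atp6v0c, with 1 wild-type UMI (171; 30.5 to 6765), and Cpne1, with 1 (39.3; 6.87 to 1571), while Chtf8, Mndal and Ifi203 did not pass. The test was edgeR's quasi-likelihood test, with 5355 genes at an unadjusted p under 0.05. The count was 1137 without wild-type library 2 and 3711 without wild-type library 3, and without TMM, which shifted the median by 0.35, the split was 2878 rises and 295 falls. With DESeq2 it was 1896 and 1151, and with limma-voom 3155 and 1640; among genes with at most 5 kb of intron it was 96 and 140.

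Fibroblasts also carried changes in the same libraries, and most of those named below went the same way in epithelium. Of 6414 genes, 577 rose and 157 fell. Xkr4 and the mitochondrial import gene Timm23 were each at least 21.7-fold higher in the GOF library, March3 at least 16.1-fold, and Slc24a3 and Fdx1l at least 12.4-fold, all against 0 wild-type UMIs. In epithelium Xkr4 was 66.0-fold, Timm23 19.4-fold, March3 20.8-fold and Fdx1l 163-fold higher too, while Slc24a3 was 2.90-fold lower. The interferon-inducible gene Ifi202b was at least 58.3-fold lower, and in epithelium it had 1 GOF UMI, a ratio of 0.00162 (4.1e-05 to 0.00908). Transcripts of pancreatic enzymes and secretory proteins were lower: Rnase1 at least 45.0-fold, Cpb1 44.3-fold, Sycn 42.8-fold and the lipase Pnlip 34.7-fold. Ifi202b and these transcripts were each at 0 in GOF fibroblasts. Wild-type library 3 held most of these transcripts; without it the bounds were 20.01, 16.7, 10.0 and 5.56, Rnase1 and Cpb1 did not pass (edgeR adjusted p = 0.104 and 0.181), and Sycn and Pnlip were too sparse to be tested. Slc24a3 and Fdx1l did not pass without wild-type library 1 (0.0892 for both). Pancreatic genes fell in 4 of 6 tested members (5 adjusted over the list alone; camera adjusted p = 0.00116, adjusted p = 0.862 with an estimated correlation). Pancreatic-like cells made up 0.0217% of GOF cells and 0.647%, 0.207% and 6.13% of wild-type cells. The pancreatic transcripts were not particular to fibroblasts. In epithelium Rnase1 was 29.1-fold, Cpb1 247-fold, Sycn 26.5-fold and Pnlip 186-fold lower. Before TMM, Prss2 in wild-type libraries 1, 2 and 3 was at 37.5, 9.52 and 227 CPM in fibroblasts. In T, NK and innate lymphoid-like cells it was at 117, 17.8 and 326. These falls therefore cannot be read as changes of fibroblast expression. Glutathione genes (median -0.62, 1 fall of 14) and oxidative phosphorylation (median -0.52, 0 falls of 22 by edgeR) passed camera at adjusted p of 0.0235 and 0.0266, again 0.862 with an estimated correlation. With DESeq2 the fibroblast counts were 143 and 83, in separately clustered libraries 930 and 562, and without TMM the median shifted by 0.12.

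Epithelial and fibroblast fold changes ran in parallel. Across 6254 genes, which are not independent replicates, Spearman's rho between them was 0.748 and the covariance 0.9902. When each wild-type library in turn was set against the other two, rho was 0.313, 0.0884 and 0.264 and the covariance 0.0967, 0.0384 and 0.120. Both comparisons use the same control libraries, so part of the excess may come from them. Shared rises numbered 394 where independent lists would share 72.1, and shared falls 87 where they would share 9.13. Fold changes also followed intron length: rho across genes was 0.401 in epithelium and from 0.401 to 0.598 over the 9 classes tested, against at most 0.223 in size for a wild-type library set against the others.

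**Figure D3:**
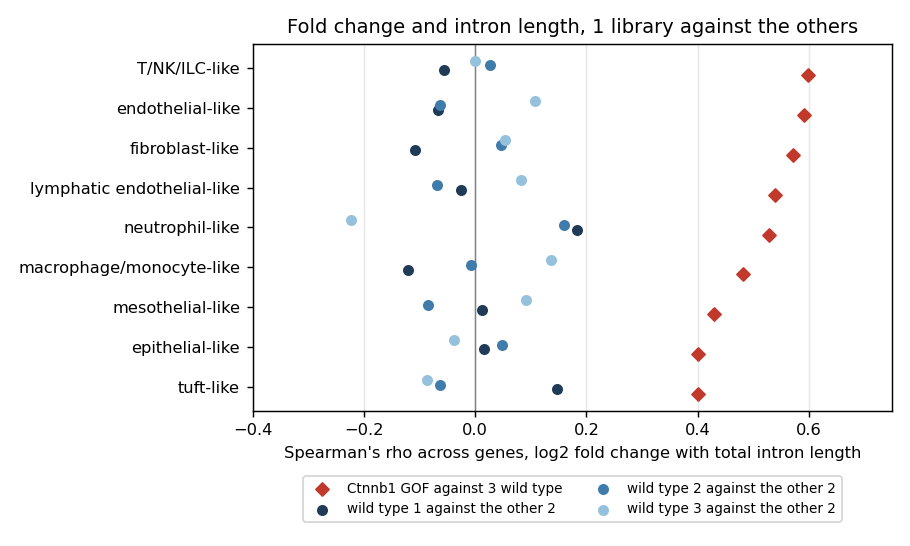
Spearman's rho across genes between log2 fold change and total intron length, per cell class, with GOF against wild type as diamonds and each wild-type library against the other two as circles. GOF values lay between 0.401 and 0.598, and the wild-type values were at most 0.223 in size.

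To set aside what both compartments shared, the epithelial effect was compared with the fibroblast effect within libraries. Nkd1 (8.90), Sp5 (6.37), Notum (6.08) and Axin2 (4.56) had larger GOF effects in epithelium, 4 of 11 tested feedback genes, as did 6 of 26 Wnt targets (9 adjusted over the list alone). Znrf3 did not differ by the test (-0.81, edgeR adjusted p = 1), and its fibroblast log2 fold change was 3.38. The xenobiotic enzyme Cyp1b1 (6.47) and the ciliary gene Cfap43 (7.19) followed the epithelial direction, while Mndal (-3.64) and Ifi203 (-4.38) were lower in epithelium alone of the 2 classes. Immediate early genes passed in 10 of 22 members, interferon-response genes in 7 of 21, antigen-presentation genes in 2 of 17 and pericentral genes in 2 of 9. Adjusted over the list alone these were 13, 9, 8 and 3. Of the feedback list only 3 members were tested in both single-class comparisons, so its camera result rests on few fibroblast UMIs. Camera's adjusted p was 0.0328 for the feedback list, 0.000369 for Wnt targets, 1.54e-09, 3.56e-08, 6.27e-06 and 0.000387 for the other 4 in the same order, and at least an adjusted p = 0.576 with an estimated correlation. Several of the remaining genes rested on empty sums: Slc24a3 (-13.61) and Pde1c (-10.67) had 0 wild-type fibroblast UMIs and were at least 12.4-fold and 11.3-fold higher in GOF fibroblasts, and the pancreatic transcripts Reg2 (11.42) and Pla2g1b (9.97) had 0 GOF fibroblast UMIs and were at least 24.3-fold and 17.0-fold lower there. All 33 wild-type fibroblast UMIs of Reg2 and 19 of the 23 of Pla2g1b lay in wild-type library 3; without it Reg2 (2.10) and Pla2g1b (9.53, bound 4.45-fold) did not pass, and neither did Sp5 (5.59), Cfap43 (6.004) and St6galnac5 (-4.33). Pde1c did not pass without library 1, 2 or 3 (-10.46, -10.90 and -11.26), and St6galnac5 was at -13.00 without library 1. Cpa1 (-6.26), the oxidase Nox4 (-6.17) and St6galnac5 (-5.15) completed the named genes. Cpa1 and Nox4 rested on 2 GOF epithelial UMIs each, ratios of 0.00395 (0.000477 to 0.0144) and 0.0975 (0.0110 to 0.407) in epithelium. St6galnac5 rested on 2 wild-type fibroblast UMIs, a ratio of 9.49 (2.47 to 80.9) in fibroblasts.

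In all, 110 of 14490 genes had a higher and 56 a lower GOF effect in epithelium by edgeR's quasi-likelihood test with the library as a block. DESeq2 gave 28 and 8, thinned cells 23 and 3, separately clustered libraries 408 and 397, and the fit without the block 0 by edgeR with 737 at an unadjusted p under 0.05. Against the 3 cell classes used as comparators, the count ran from 53 with endothelial-like to 481 with macrophage-like cells, and without TMM the median shifted by 0.17.

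To ask how many epithelial cells carried the Wnt feedback signal, cells were thinned to 2000 UMIs. At least 1 of the 11 feedback genes was detected in 55.1% of GOF cells (53.5 to 56.7%; 2096 of 3805 cells) and in 12.2% ± 3.20 of wild-type cells (n = 3). At least 2 were detected in 28.4% and 0.621% ± 0.294, and 3 or more in 494 GOF cells and in 0, 1 and 0 wild-type cells. Axin2 was detected in 16.4% of GOF cells and 0.9503% ± 0.392 of wild-type cells, Nkd1 in 15.0% and 0.0505% ± 0.0874, Sp5 in 9.49% and 0.137% ± 0.154, Notum in 5.02% and 0.166% ± 0.0539, and Lgr5 in 3.78% and 0.113% ± 0.166. Rnf43 was at 22.2% against 6.58% ± 2.34 and Znrf3 at 28.6% against 4.70% ± 0.814; without Znrf3 the share with at least 1 gene was 44.5% against 8.01% ± 2.61. Tcf7 was at 1.45% against 0.125%, Lef1 at 0.631% and Apcdd1 at 0.315% against 0.00%, and Wif1 at 0.0526% against 0.0119%. The proliferation markers Mki67 (2.44% against 1.01% ± 0.255) and Top2a (3.07% against 0.652% ± 0.368) were likewise more often detected.

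Macrophage-like cells, which should lack these genes, had at least 1 in 5.71% of GOF cells (median 7819 UMIs; GOF epithelium 8730.0) and in 1.07% ± 0.987 of wild-type cells (medians 4790, 3975 and 2357; wild-type epithelium 7472.5, 3537.0 and 2426.5). In macrophage-like GOF cells the shares were 0.416% for Axin2, 0.714% for Nkd1, 3.09% for Znrf3 and 0.119% for Apcdd1, so Apcdd1 and Wif1 in epithelium were not separable from background. Tuft-like cells had at least 1 gene in 56.98% of GOF cells and 21.7% ± 1.66 of wild-type cells, and fibroblasts in 32.8% and 13.01% ± 3.65. Endothelial-like cells, with 54 GOF cells at this depth, had at least 1 gene in 46.3% and 24.5% ± 6.83, with Znrf3 in 16.7% and 0.00%. In T, NK and innate lymphoid-like cells, not thinned and so not at equal depth, the shares were 71.4% and 25.5% ± 3.92. Znrf3 was at 33.2% and 2.63% ± 0.989 there, Lef1 at 31.1% and 5.43% ± 1.81, and Tcf7 at 31.1% and 17.1% ± 2.24. In endothelial-like cells Lef1 was at 33.3% and 18.4% ± 10.3. Wild-type cells of both classes thus already held Lef1 or Tcf7, so these shares do not measure Wnt feedback alone. More frequent detection in the GOF library, Znrf3 included, was still not confined to epithelial types. Thinning left out 298 GOF epithelial cells and 153, 180 and 371 wild-type cells; the unthinned shares with at least 1 gene were 81.1% and 31.0% ± 2.69. There is no test across cells, and 44.9% of GOF cells with no feedback gene at this depth cannot be read as cells without the allele.

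**Figure D4:**
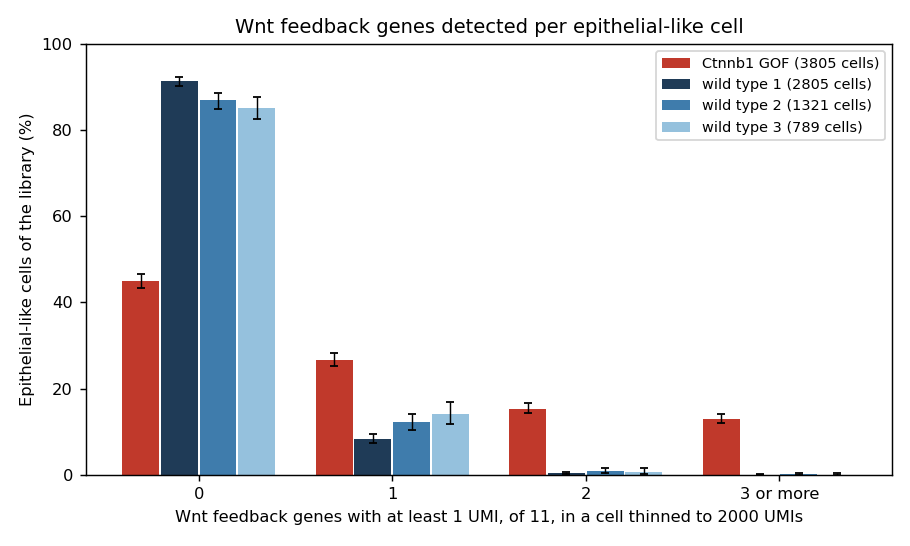
Percent of epithelial-like cells of each library with 0, 1, 2 or at least 3 of the 11 Wnt feedback genes detected after thinning to 2000 UMIs (bars, share; lines, exact 95% binomial interval). In the GOF library 12.98% of cells had at least 3 genes, against 0.00%, 0.0757% and 0.00% in the wild-type libraries.

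Cell class shares differed between single libraries by more than the test could resolve. Macrophage-like cells made up 19.2% of GOF cells (18.4 to 20.1%) and 5.77% ± 2.96 of wild-type cells, a log2 fold change of 1.74 (edgeR adjusted p = 0.752). Epithelial-like cells made up 44.6% (43.5 to 45.6%) and 62.3% ± 5.96, tuft-like cells 1.98% and 2.93% ± 0.531, fibroblast-like cells 3.44% and 4.88% ± 3.75, mesothelial-like cells 8.11% and 6.59% ± 4.32, and T, NK and innate lymphoid-like cells 2.62% and 1.44% ± 0.222. Neutrophil-like cells made up 3.77% against 14.3%, 1.28% and 1.46%. Of 14 classes, 0 passed by edgeR's quasi-likelihood test and 0 had an unadjusted p under 0.05; no other tool was run. Without wild-type library 1, pancreatic-like cells passed with a lower share in the GOF library. GOF macrophage-like cells lay mostly in cluster 4, led by Lyz1, Ccl9, Cd36 and Mmp12, and wild-type ones in clusters 7 and 23. Counted before doublets were left out, 1401 of the 1407 cells of cluster 4 were GOF cells. Shares compare cells recovered after dissociation, and 10.1% of GOF cells were left unnamed.

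Epithelial-like cells were clustered again into subclusters to see whether cells of the GOF library mixed with the wild type. Of GOF cells, 96.2% lay in subclusters with at least 95% GOF cells, which may be the library and not a state. The largest held 1871 cells, led by Lsamp, Kcnh7 and Hbegf; another held 1209 cells, led by Nkd1, Axin2, Tnfrsf19 and Serpinb11; a further 572 cells were led by Gkn3, Rgs5 and Muc6, of which Gkn3 and Muc6 are genes of gastric glands; and 295 cells of low UMI count (median 1327) were led by AY036118, a transcript of ribosomal RNA origin, Reg3b and Reg3g, with Gm42418, Saa3 and Lyz2, a macrophage gene, also among their leading genes, so they may be of low quality or hold background. Cycling cells led by Ube2c, Top2a and Mki67 formed a shared subcluster of 141 GOF cells and 55, 9 and 6 wild-type cells. Cells with Foxi1 and Atp6v1g3, genes of ionocytes, also came from all 4 libraries, with 6, 8, 11 and 3 cells.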

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

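The tests of Wnt feedback genes and of immediate early genes against library-wide causes, the tests of depth on the interaction, of introns on Nkd1 and Axin2 and of sex were chosen after the results were seen; the other tests were written before. The results below stood out because the GOF effect differed between epithelial-like and fibroblast-like cells by an interaction test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted), or because a signal lay in data that the comparisons left out. The interaction test found 166 genes.

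Wnt feedback genes rose in GOF epithelium, and 4 had larger GOF effects there than in fibroblasts: Nkd1 by 8.90, Sp5 by 6.37, Notum by 6.08 and Axin2 by 4.56 on the log2 scale, with medians of 1.55 for the feedback list and 1.40 for Wnt targets, both lost by camera with an estimated correlation; without the replicate block no gene passed by edgeR, with 737 at an unadjusted p under 0.05. The median of the feedback list rested on few fibroblast UMIs, as only 3 members were tested in both classes. In GOF and wild-type fibroblasts Tcf7 had 5 and 1 UMIs, Lgr5 2 and 0, and Lef1 0 and 0. A library-wide cause, such as the software or the gene reference, is argued against for Nkd1 and Axin2, and more weakly for Notum. Their differences passed without each wild-type library and were at least 4.27 wherever the comparator class held a wild-type UMI. Notum rested on 15 GOF and 15 wild-type fibroblast UMIs, and 11 of the latter lay in wild-type library 3. Without that library 4 were left, and the difference was 5.24 (SE 1.43). Reversals occurred only where the comparator class held no wild-type UMI. They were Notum with the stricter filter (-2.64) and against endothelial-like (-4.32) and macrophage-like cells (-3.62), and Axin2 against macrophage-like cells (-4.79). For Sp5 this cause and the genotype cannot be told apart with 7 GOF and 6 wild-type fibroblast UMIs. The Sp5 difference was at least 3.67 by the same rule and was not past the threshold without wild-type library 3. Depth is argued against for the rise in epithelium, since 7 of the 7 members tested after thinning to equal UMIs and cell numbers still rose; for the difference between the classes thinning leaves too few fibroblast UMIs to decide, with 1.0 of the 4 genes past the threshold, Nkd1 (9.82, SE 2.06, against 8.90, SE 0.896), Axin2 about as large as before with a wider error (4.35, SE 1.41, against 4.56, SE 0.542), and Notum (5.55) and Sp5 (-1.29, SE 4.17) without a wild-type fibroblast UMI. Counting of introns is argued against as the whole cause for Notum and Sp5, which have less intron than the median gene (17563 bp) and rose by 5.08 and 5.34, a median of 5.21, and for Nkd1 and Axin2, since it would act in fibroblasts too, while the lower of their differences was still 3.47 after taking off 2 SE. Sex as the whole cause is argued against, since GOF cells with Y-linked RNA and no Xist had at least 2 feedback genes in 22.8% (20.6 to 25.1%), against 0.621% ± 0.294 of wild-type cells, whose libraries held almost no Xist; strain, age and housing were not tested, and beta-catenin activation in epithelium stays a hypothesis from 1 GOF library.

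For the 7 feedback members whose effects were not shown to differ between the classes, a library-wide cause and the genotype cannot be told apart: their median difference was 0.41 and only 2 were tested in fibroblasts. Among them, Znrf3 had a difference of -0.81 and a fibroblast log2 fold change of 3.38 that rested on 3 wild-type UMIs, and Apcdd1 had 29 GOF fibroblast UMIs against 0.

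Genes with long introns were higher in the GOF library in every class tested. The correlation across genes between fold change and intron length had a lowest rho of 0.401 over 9 classes and a highest of 0.598, and genes are not independent replicates. Depth is argued against, since after thinning to equal UMIs and cell numbers the lowest rho over 5 classes was still 0.357. The values that intronic counting in the GOF library alone would need are there, and the newer software version in the GOF file header is consistent with it; whether introns were counted is not given in the sources used here. Genes with at most 5 kb of intron had a median epithelial log2 fold change of -0.37 and the others 0.12. A GOF fall of a gene with little intron may thus be part of this shift. A GOF rise of a long gene may therefore be part of this shift, and among genes with at most 5 kb of intron 236 changed in epithelium.

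Immediate early genes had larger GOF effects in epithelium, by a median of 1.46, with Atf3 at 3.03, Dusp1 at 2.68 and Btg2 at 1.68. A cause in handling or dissociation that acts on the whole library and an epithelial response cannot be told apart: the list's median was above 0 in each of 9 classes, with 0.49 as the lowest and 2.39 as the highest of the other classes, while the difference between epithelium and fibroblasts passed by camera with the preset correlation (adjusted p = 1.54e-09) and not with an estimated one (adjusted p = 0.576), with 10 of 22 members past the threshold by edgeR. Cells of different types may respond to the same digestion to different degrees, which keeps it open.

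Among the other lists, interferon-response genes differed by a median of 1.76, antigen-presentation genes by 1.30 and pericentral liver genes by 1.08; these passed camera with the preset correlation alone, and with an estimated correlation the adjusted p was 0.6797, 0.6797 and 0.6402. Mitotic genes differed by -3.18, but only 2 members passed the count filter in fibroblasts, so that value rests on nearly empty sums. Cyp1b1 differed by 6.47 and Cfap43 by 7.19. Wnt5b differed by 5.10, Cyr61 by 2.85, Icam1 by 2.18, H2-Q7 by 3.67, Cdkn1a by 2.70 and Id1 by 2.21. Mndal differed by -3.64 and Ifi203 by -4.38, both interferon-inducible genes of a family with many near-identical members. Slc24a3 (-13.61), Pde1c (-10.67), Reg2 (11.42) and Pla2g1b (9.97) each had a fibroblast group with no UMI, so these fitted values are not bounds. Cpa1 (-6.26) is a pancreatic transcript, and Nox4 (-6.17) and St6galnac5 (-5.15) were the remaining named genes. Cpa1 and Nox4 rested on 2 GOF epithelial UMIs each and St6galnac5 on 2 wild-type fibroblast UMIs.

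Outside the shared gene reference lay 0.508% of the UMIs of the GOF library, against 0.0856%, 0.0921% and 0.104% in the wild-type libraries. Gas5 (43123 UMIs) and Anxa13 (33807 UMIs) held the most, since their identifiers are listed in the GOF reference alone. Clusters without a class name held 10.1% of GOF cells. The largest, with 898 GOF cells of 904 counted before doublets were left out, had a median of 1781 UMIs and scored nearest to epithelium.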

How the results depend on the processing

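Tests on genes with at most 5 kb of intron, of lists in the interaction fit, without cycling clusters and without Znrf3 were chosen after the results were seen. No paired analysis was possible because the lone GOF library has no wild-type partner in the labels.

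The epithelial comparison called 2340 genes and stayed within 1.5 times that count in 9 alternatives with all libraries, from 1742 to 3173, and at 2047 without wild-type library 1. It gave 1449 with thinned cells, 236 with short introns and 4795 with limma-voom, with fewer genes tested in the thinned and short-intron sets. Leaving out wild-type libraries in turn gave 1137 to 3711. The fibroblast comparison (734) gave 226 with DESeq2, 74 with at least 10 UMIs in 3 libraries, 1492 with libraries clustered on their own, 109 with thinned cells and 104 with short introns, and 582 to 916 with a library left out.

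The interaction (166) gave 36 with DESeq2, 6.0 with at least 10 UMIs, 98 with the stricter cell filter, 805 with libraries clustered on their own, 26 with thinned cells, 43 with short introns, 53 against endothelial-like and 481 against macrophage-like cells, and 136 to 169 with a library left out. Without the replicate block it gave 0.0 by edgeR, with 737 at an unadjusted p under 0.05. For the wild-type compartments, 58 pathway genes passed, 55 without the replicate block and 50 to 66 over the alternatives. Except where fewer genes were tested, the cause was not tested.

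Class shares (0.0 past the threshold) gave 1.0 with the stricter filter, 1.0 with libraries clustered on their own and 0.0 to 1.0 with a library left out. The Wnt target list had the same median, 2.26, with an estimated correlation, at an adjusted p = 0.444; its other alternatives passed, with medians of 1.40 to 5.04. The share difference for at least 1 feedback gene (42.9 points) was 31.8 at 1000 UMIs, 47.6 at 4000 UMIs, 50.1 unthinned, 34.7 with the stricter filter, 39.4 with libraries clustered on their own, 36.5 without Znrf3 and 41.1 to 44.2 with a library left out. The share of GOF cells in GOF subclusters (96.2%) was 95.4% at resolution 1, 95.5% with doublets kept and 95.5% without Wnt target genes. The cause was not tested.

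In the interaction fit the list medians changed sign for mitotic genes (-3.18), glycolysis (0.0152) and intestinal genes (0.0347). Prom1, which did not pass, gave 0.0305 without TMM and 0.0105 with the stricter filter. Against endothelial-like cells Cyp1b1 (-4.75), Pde1c (0.26), Cpa1 (3.49) and Notum (-4.32) reversed, and against macrophage-like cells Axin2 (-4.79), Notum (-3.62) and Sp5 (-2.96), none past the threshold. Notum gave -2.64 with the stricter filter and Sp5 -1.29 with thinned cells. Axin2, Notum and Sp5 had 0 wild-type macrophage UMIs against 56, 47 and 30 in the GOF library, and the other reversals of Notum and Sp5 also had 0 wild-type UMIs in the comparator, so these rest on empty sums; for Cyp1b1, Pde1c and Cpa1 the cause was not tested. Of the values of named genes under the alternatives, 1146 of 1256 in epithelium, 76 of 88 in fibroblasts and 103 of 169 in the interaction had the same direction and side of the threshold, and 108, 12 and 57 had the same direction without passing; for lists these were 79 and 26 of 108. Depth limits the small classes: wild-type library 2 held 209988 fibroblast UMIs, and wild-type library 3 held 27594 in T, NK and innate lymphoid-like cells.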

Other observations

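The tests within the GOF library below were all chosen after the results were seen; the count of splits was planned. Within GOF epithelium, cells with at least 2 Wnt feedback genes after thinning (1079 cells) differed from cells with none (1709 cells) in genes outside that list. Serpinb11 was 10.6 times (counting interval 7.46 to 15.4), Cyp1b1 10.6 times, Adamtsl3 10.2 times and Tnfrsf19 11.1 times as high, and the proliferation genes Mki67 (2.75 times; 1.72 to 4.46) and Top2a (2.41 times) were higher. The cyclin gene Ccnd1 went the other way, at 0.652 times (0.578 to 0.733). Among genes with at least 50 CPM in the higher set, the 10 most lowered were the neutrophil chemokine Cxcl5, at 0.157 times (0.129 to 0.189), Nkain2 (0.154), the goblet cell peptide Tff3 (0.170), Reg1 (0.189), Akr1b7 (0.184), the mucin Muc13 (0.192), Scgb3a1 (0.214), Sptssb (0.227), Bace2 (0.231) and Spink4 (0.238). These cells come from 1 library with 1 reference and 1 depth, so software and depth are held constant, but cells are not replicates and no p-value is given.

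Lists differed as well, set against random lists of genes of like expression. The random genes were drawn independently of each other, so their range ignores co-expression within a list. It is also not adjusted for the number of lists compared. A median outside it is therefore not a test result. Injury genes had a median log2 ratio of -0.84 (95% of random lists of the same size: -0.15 to 0.16), intestinal genes -0.84, gastric mucous genes -0.71 and mesenchymal genes -0.59, while mitotic genes stood at 0.76 (random lists -0.15 to 0.33). Smaller medians outside the range of random lists were those of Wnt ligands (-0.42, on 5 members), bile acid genes (-0.27), biliary identity (-0.18) and oxidative phosphorylation (-0.18), all lower. Those of Wnt receptors (0.39), replication (0.33), Hedgehog and BMP genes (0.29) and ribosomal proteins (0.14) were outside it too, all higher. Immediate early genes (0.02) and interferon-response genes (0.17) lay inside the range of random lists, and Atf3 stood at 1.13 times. Immediate early genes thus did not follow the Wnt genes from cell to cell. For interferon-response genes this stays open. Their median was -0.14 in cells with Xist alone and -0.15 in cells with Y-linked RNA alone. Both lay below the range of random lists over all cells (-0.11 to 0.27). Ctnnb1 (1.06) and Prom1 (1.07) hardly differed. Genes and cells were grouped by detection of the feedback genes, so cell states with more feedback RNA are compared, not cells known to carry the allele.

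The GOF library held cells of both sexes. Of 4103 GOF epithelial cells, 1700 had Xist and no Y-linked UMI, 1408 a Y-linked and no Xist UMI, 241 both and 754 neither, and Xist stood at 597 CPM in GOF epithelium against 0.740, 2.18 and 1.46 in the wild type. At least 2 feedback genes were detected in 36.4% (34.1 to 38.8%) of cells with Xist alone and 22.8% (20.6 to 25.1%) of cells with Y-linked RNA alone. Injury genes were lower in cells with feedback genes in both sets (-0.72 and -1.02), as were intestinal (-0.83 and -0.63) and gastric mucous genes (-0.77 and -0.35). The mitotic median was 1.31 in cells with Y-linked RNA alone. In cells with Xist alone it was 0.32, inside the range of random lists over all cells, the only range drawn. Of the smaller medians, those of replication (0.08 and 0.26) and Wnt receptors (0.27 and 0.22) lay inside that range in both sets, and those of bile acid genes (-0.08) and oxidative phosphorylation (-0.12) in cells with Xist alone, so the composition of the GOF cells stays open as their source. Animals of different sex and different recombination could give such a difference between the sets; feedback genes without Znrf3 differed from the wild type by 36.5 points in all GOF cells together.

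Wild-type epithelium held subclusters whose numbers differed between libraries. Cells with pancreatic RNA such as Ctrb1 and Prss2 numbered 35, 16 and 944 in wild-type libraries 1, 2 and 3 and 1 in the GOF library. They made up 81.4% of the epithelial-like cells of wild-type library 3. In that library Prss2 was also at 227 CPM in fibroblasts and 326 in T, NK and innate lymphoid-like cells. This subcluster is therefore not shown to be an epithelial state. Cells led by Nos2, Cxcl5 and Lcn2 numbered 1356, 293 and 1 in the wild-type libraries and 0 in the GOF library. Subclusters split largely by library, so the count of 0 may follow from the clustering. Among all cells, doublets included, cluster 29, led by Cxcl5 and Nos2, held 1504, 330 and 6 wild-type cells and 30 GOF cells. Goblet-type cells led by Clca1, Zg16 and Muc2 numbered 20, 2 and 7 against 1.

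For the wild-type compartments, splits of the 6 sums into 3 and 3 numbered 10, too few for a share under 0.05. The split by compartment called 55 pathway genes without the block and the highest of the others 0 (4 at an unadjusted p under 0.05); 1 of the splits, the real one, gave as many.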
